A study of Mus musculus with 8 samples.

How the data were processed

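Anti-IRF5 CUT&Tag (antibody ab21689 of abcam, per the series' design text) was run on wild-type mouse bone marrow-derived macrophages treated with PBS (control) or CpG, with 2 libraries per condition. The series holds 8 samples, of which 4 are IgG libraries without a peak list of their own, and these were not analysed here. The dose and duration of CpG are not given in the labels. Cells were thawed, bound to concanavalin A beads, permeabilised with digitonin and tagmented with a protein A-Tn5 fusion, per the labels' protocols. Reads were processed with fastp 0.20.0, BWA 0.7.12, MACS2 2.1.0 and ChIPseeker, per the submitters' processing notes, which give no genome build and no version of ChIPseeker.

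The deposited data used here are 6 annotated peak lists, 4 of single libraries and 2 of whole conditions. Each peak has a pileup, the signal at its summit, as deposited by the authors, and this was a whole number for 100% of peaks. Each also has a fold enrichment, the ratio of that pileup to the local background as computed by the authors' peak caller. The significance of a peak was deposited by the authors as the −log10 of its p-value and of its q-value, where damaged column headers were read from their order and values. The lowest −log10 p was 5.00 to 5.02 in the 4 lists. Per the names of the deposited files, both control libraries were called against 1 IgG library of the control and both CpG libraries against 1 IgG library of the CpG condition, so the background library follows the condition. Lines that continued an overlong annotation cell were skipped (875, 1017, 281 and 682 in control 1, control 2, CpG 1 and CpG 2, and 829 and 393 in the lists of the control and CpG conditions). Peaks on the 21 assembled nuclear chromosomes were used, which left out 15, 17, 13 and 16 peaks on other contigs.

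Because the lists hold no read counts comparable between libraries, no model was fitted to peak heights, and fold enrichments were used to rank or describe peaks within a list and are not compared between lists. Depth is unknown. A relative estimate was made by dividing the background pileup implied by pileup and fold enrichment (0.989, 1.01, 1.31 and 0.886) by the shortest peak (140, 141, 130 and 139 bp), which stands for the fragment length. No confidence interval can be given for peak numbers, and the precision of each comparison is limited by 2 libraries per condition.

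Peaks of the 4 libraries were merged into regions where they overlapped by at least 1 bp, and Jaccard indices were computed with bedtools 2.31.1. A region or gene was called CpG-only when found in both CpG libraries and neither control library, and control-only in the opposite case. A gene counted as promoter-bound when the authors' annotation put a peak in its Promoter class. That class was found to follow the summit, as 97.5% to 97.9% of peaks with a summit within 2 kb upstream of the nearest gene's start were in it. Of 9258 promoter genes 8442 had a name in the files, and 816 IDs without one stayed in the counts and out of the list tests. A name is given only for the nearest gene of a peak. List members that were nearest to no peak in any list were therefore left out of the tests and shares. Of 20824 named genes 16311 matched a symbol of the RefSeq table of GRCm38.p6, which was used for gene type alone, since only 3.11% of the matched genes started within 1 kb of the same position there.

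Peak numbers and annotation shares were compared by a two-sided exact permutation test over the 6 assignments of 4 libraries to 2 conditions, with a smallest p of 0.333. Overlaps and group-only counts were set beside the other 2 of the 3 splits of the libraries into pairs. Each of 24 gene lists was tested per library by a two-sided Fisher's exact test of promoter-bound members against all other named genes, with Benjamini-Hochberg adjustment over 96 tests, and counted where adjusted p was under 0.05 in both libraries of a condition. The balance of each list between CpG-only and control-only named genes was tested by Fisher's exact test, adjusted over the lists. Genes are not replicates, so these tests describe the libraries. The lists cover interferon-stimulated genes, type I interferons, the IRF family, inflammatory cytokines and chemokines, NF-kB subunits and targets, TLR9 and MyD88 signalling, immediate early genes, antigen presentation, cell death and inflammasome, lysosome and phagocytosis, glycolysis, oxidative phosphorylation, alternative activation, macrophage identity, cell cycle, ribosomal proteins, housekeeping, genes of unrelated tissues, and markers of dendritic cells, B cells, T and NK cells, neutrophils and granulocytes, erythroid cells and megakaryocytes, and stromal and endothelial cells.

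The designs, lists, alternatives and genes to be named were chosen before the data were examined, except where stated. Named were 24 fixed genes whatever they showed, the 8 CpG-only and the 8 control-only promoter genes with the highest lower percentile by fold enrichment within the lists, up to 4 members of each fixed list per direction, and the 5 genes with the highest lowest percentile in all 4 libraries, leaving out predicted genes, pseudogenes and small RNA genes from the ranked parts. Members of the lists bound in all 4 libraries were named afterwards as examples. The alternatives were a −log10 q of at least 5, the 13553 highest peaks of each library, an overlap of 50% of the shorter peak, a peak within 1 kb of the start site or any nearest peak in place of the Promoter class, all contigs, the authors' lists of whole conditions, each library left out, and the replicate number as a block. Added after seeing the data were backgrounds of RefSeq symbols and of protein-coding genes, control 2 and CpG 2 alone, and the exclusion of genes whose peaks overlap one of the other condition. A search for IRF motifs needs a genome sequence, which was not used here, and was not run.

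The procedures were tested on simulated data. All 100% of 6000 simulated region patterns were recovered. The simulated sites lay far apart and the peaks of a site always overlapped, so recovery was bound to succeed. Peaks that chain together or break up were not simulated. The simulations used names of the 4 library lists alone, so gene numbers are slightly below the 20824, and the 127 CpG-only and 908 control-only, of the tests themselves. Among 20755 genes, lists of 30 drawn without a difference were called, before adjustment, in 6.5% of 200 trials in control 2 and 3.5% in CpG 1, and lists drawn at odds of 3 in 90.5% and 70%. In the balance test, simulated on 1033 genes, lists of 5 members, the most that any list had, were called in 1% of trials without a difference and in 30.5% at odds of 5, and lists of 15 members, longer than any here, in 3.5% and 80.5%. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.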

Results

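The binding of IRF5, an interferon regulatory factor that acts downstream of MyD88 in the Toll-like receptor pathway, was mapped by CUT&Tag in wild-type mouse macrophages grown from bone marrow. In CUT&Tag an antibody brings a transposase to the DNA next to the target protein, and the fragments released there are sequenced. Cells had received PBS, here called control, or CpG, unmethylated DNA that is recognised by the receptor TLR9. Each of the 2 conditions had 2 anti-IRF5 libraries. Of the 4 IgG libraries of the series, 1 per condition was the background of the authors' peak calls, judged by the names of the lists. The background therefore follows the condition in every comparison below. The deposited lists held 29226 and 37315 peaks on the assembled nuclear chromosomes in control 1 and control 2, and 13553 and 25851 in CpG 1 and CpG 2. The lists give no read totals. A depth estimated from each list's background pileup and shortest peak was 1.11 for control 1, 1.13 for control 2 and 1.59 for CpG 1 relative to CpG 2, so the library with the fewest peaks had the highest estimate. Nothing in the labels says whether the libraries came from separate animals or cultures. The exact permutation p-values below set the conditions against the spread between these libraries, which may be technical. Those of Fisher's exact test compare genes within a library or between sets of genes, and do not measure that spread.

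**Figure D1:**
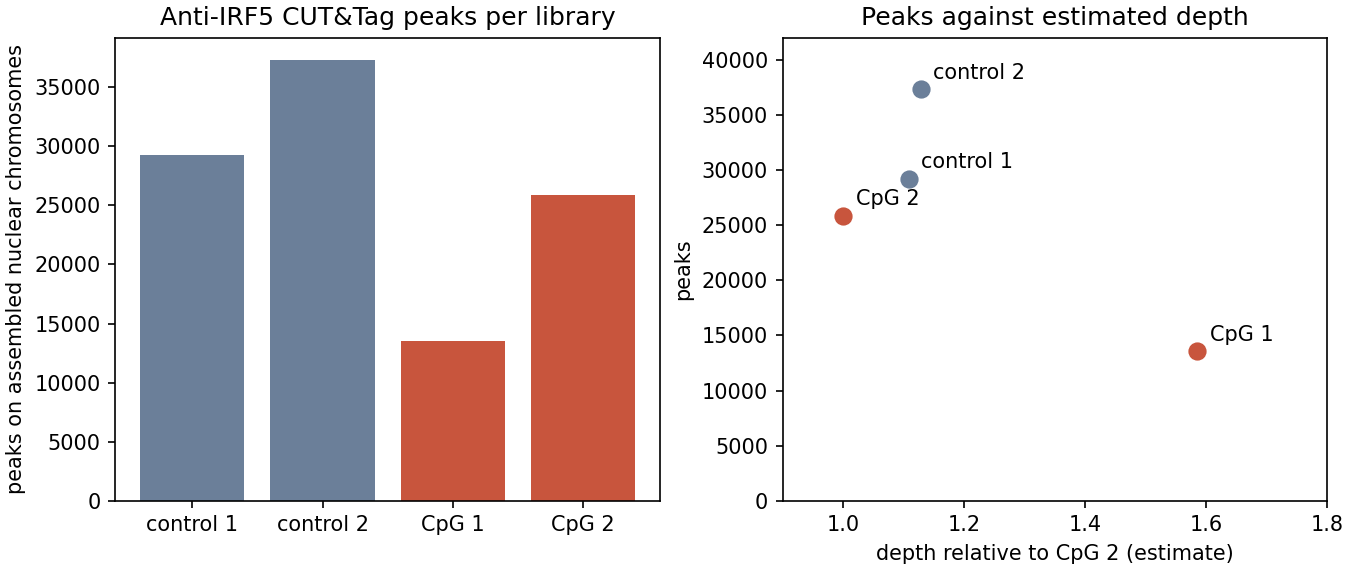
Peaks per anti-IRF5 library on the assembled nuclear chromosomes (left, bars), and the same numbers against the depth estimated relative to CpG 2 (right, 1 point per library). CpG 1 has 13553 peaks and the highest estimated depth, 1.59.

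The chemokine genes Ccl12, Pf4 and Ccl3 were among the 5 genes with the highest lowest percentile, by fold enrichment within each list, of those with a promoter peak in all 4 libraries. Of 9258 genes with a promoter peak in any library, 1247 had one in all 4. Ccl12, a chemokine that attracts monocytes (chromosome 11, 81992670 to 81994226), had promoter peaks with fold enrichments of 28.2 in control 1, 90.6 in control 2, 18.2 in CpG 1 and 78.5 in CpG 2, and these lay at or above the 99.8 percentile of each list. The next genes by their lowest percentile were Pf4, which encodes platelet factor 4 and is in the list of erythroid and megakaryocyte markers (98.7), Ccl3, a chemokine also known as MIP-1 alpha (97.5), Eapp (97.2) and Necap1 (95.8). The promoter peak of Eapp had another gene as its nearest in every library. Eapp was the nearest gene only of 1 peak in control 1, with a fold enrichment of 6.76 against 13.4 for its promoter peak. A fold enrichment is the authors' value for the peak and is compared only within its own list, and positions are those of the files, whose genome build is not given in the sources used here.

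Macrophage identity genes were over-represented among promoter-bound genes in every library. Of the 34 list members, 32 were named, as the nearest gene of a peak in any deposited list, and list sizes below count such members alone. Of these, 22 and 21 had a promoter peak in control 1 and control 2, and 12 and 20 in CpG 1 and CpG 2. All named genes were bound at 24.1%, 28.6%, 10.4% and 22.2% in the same order. The odds ratios were 6.96, 4.77, 5.18 and 5.86, and Fisher's exact test, adjusted by Benjamini-Hochberg over 24 lists and 4 libraries, gave p = 5.61e-06, 0.000207, 0.00045 and 3.55e-05. Members bound in all 4 libraries were Adgre1, which encodes the F4/80 antigen, the complement genes C1qa and C1qb, Cd68, Cebpa, Maf, Msr1 and Sirpa. Immediate early genes were bound at 14, 17, 11 and 16 of 24 members, with adjusted p of 0.00174, 0.000237, 0.00017 and 7.57e-05 (Fisher's exact test), and Fos, Fosl2, Jun, Jund, Klf2, Klf4 and Myc were bound in all 4. NF-kB subunits and targets were bound at 13, 17, 11 and 16 of 28 (adjusted exact p = 0.0333, 0.00228, 0.00045 and 0.00045), with the subunit gene Rela and the regulators Bcl3, Nfkbid and Gadd45b in all 4. Genes of TLR9 and MyD88 signalling were bound at 23, 16, 8 and 17 of 33 (adjusted exact p = 3.84e-06, 0.0465, 0.0461 and 0.00129). Tlr9 itself, the adaptor gene Myd88, the kinase genes Map3k8 and Tbk1, the ubiquitin ligase gene Peli1, Hsp90b1 and Tlr13 were bound in all 4.

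Cell death and inflammasome genes, among them Nlrp3, Mcl1, Fas, Bbc3, Bcl2l11 and Nlrp1b in all 4 libraries, were bound at 15, 16, 7 and 16 of 28 (adjusted exact p = 0.00513, 0.00974, 0.0481 and 0.00045). Housekeeping genes passed as well, at 15, 20, 8 and 12 of 28 (adjusted exact p = 0.00513, 7.57e-05, 0.0203 and 0.047), with Actg1, Pgk1, Polr2a, Ubb and Vcp among those bound in all 4. Their odds ratios were 3.64, 6.25, 3.44 and 2.63. That in control 2 was above the 4.77 of macrophage identity there, and those in the other libraries were below. Whether the passing lists reflect IRF5 or promoters open to the transposase was not tested. Inflammatory cytokines and chemokines were bound at 15, 22, 14 and 20 of 39, past the threshold in all libraries but control 1 (adjusted exact p = 0.122, 0.00154, 0.000237 and 0.00045). Ccl2, Ccl3, Ccl7, Ccl12, Cxcl2, Ccrl2, Il18 and Tnf were bound in all 4. Ribosomal protein genes also missed the threshold only in control 1, at 13, 17, 8 and 15 of 34 (adjusted exact p = 0.136, 0.0327, 0.048 and 0.019). Antigen presentation genes, at 12, 14, 7 and 8 of 23, missed it only in CpG 2 (adjusted exact p = 0.345), and glycolysis genes, at 12, 15, 5 and 11 of 23, only in CpG 1 (adjusted exact p = 0.159). Dendritic cell markers, at 7, 7, 3 and 3 of 10, and lysosome and phagocytosis genes, at 13, 19, 2 and 9 of 30, passed in both control libraries and neither CpG library. That difference between the conditions was not tested in this step.

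Among the other lists, interferon-stimulated genes passed only in control 1 (18, 14, 7 and 16 of 45), with Irgm1, Trim25 and Trim30a bound in all 4 libraries. IRF family genes passed only in control 1 (6, 4, 0 and 3 of 8), cell cycle genes only in control 2 (10, 15, 2 and 11 of 29), and genes of alternative activation only in CpG 1 (6, 8, 5 and 7 of 16). The 8 remaining lists passed in no library. They were oxidative phosphorylation (8, 6, 3 and 7 of 20), markers of B cells (2, 1, 0 and 1 of 7), of T and NK cells (1, 2, 2 and 1 of 11), of neutrophils and granulocytes (2, 3, 0 and 2 of 13), of erythroid cells and megakaryocytes (1, 1, 1 and 2 of 7) and of stromal and endothelial cells (1, 2, 1 and 1 of 8), genes of unrelated tissues (1, 1, 0 and 0 of 7) and type I interferons (0 in each library, of 6). The full lists held 32, 20, 26, 24, 18, 21, 38 and 18 genes in the same order. Their other members were nearest to no peak, so the shares apply only to members with a peak near them.

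In all, 12 of the 24 lists passed in both libraries of a condition, 10 in the control libraries and 8 in the CpG libraries. These numbers depended on the genes taken as background. Against the 11335 named genes that code for proteins, a background chosen after the data were seen and bound at 33.2%, 38.8%, 14.1% and 30.5%, 3 lists passed. Macrophage identity then passed in all 4 libraries (adjusted exact p = 0.00204, 0.0261, 0.00964 and 0.00744), immediate early genes in all but control 1 (0.0838, 0.0233, 0.00578 and 0.00837), and NF-kB subunits and targets in the CpG libraries (0.00964 and 0.0261) but not the control libraries (0.355 and 0.0913), a difference between conditions that this step does not test. Without control replicate 2, 4 lists rather than 8 passed in both CpG libraries, whose own tests were unchanged. Only the adjustment, then over fewer tests, differed, and some adjusted p-values of Fisher's exact test there lay just under the threshold. With the 13553 strongest peaks of each library, 7 lists passed in a condition, 5 in each.

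**Figure D2:**
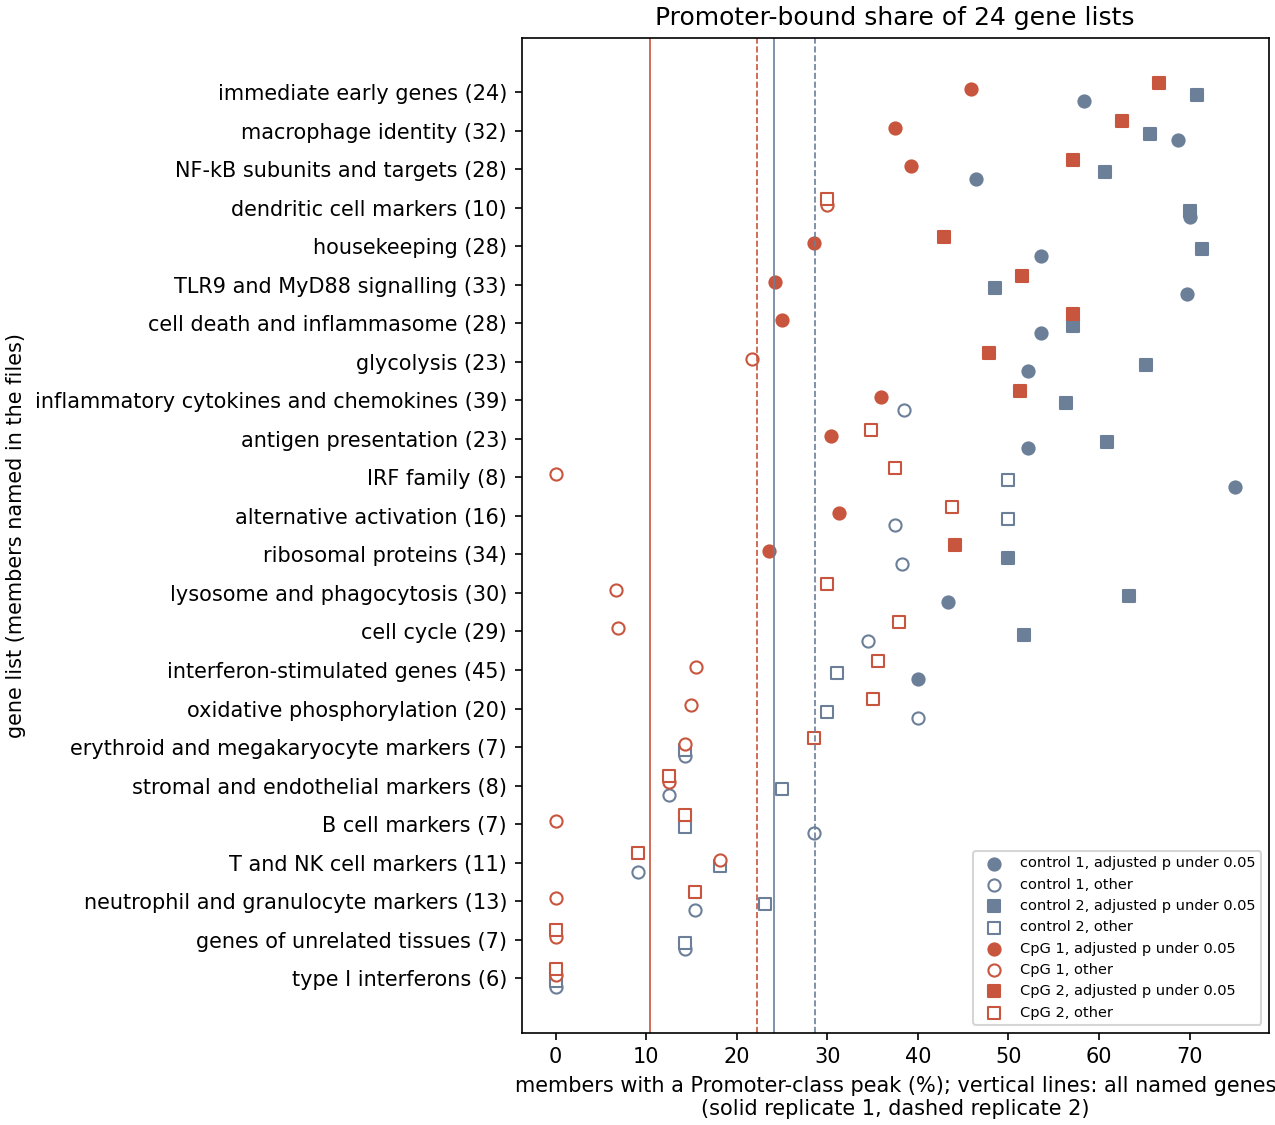
Share of each list's named members with a promoter peak, in percent, for 24 gene lists and 4 anti-IRF5 libraries. Filled points passed Fisher's exact test against all named genes at an adjusted p under 0.05, and vertical lines mark the bound share of all named genes (24.1%, 28.6%, 10.4% and 22.2%).

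The CpG libraries had fewer peaks than the control libraries, a difference that 2 libraries per condition cannot separate from the spread between replicates. Control libraries had 33271 ± 5720 peaks (SD, n = 2) and CpG libraries 19702 ± 8696 (SD, n = 2), a ratio of 0.592 (two-sided exact permutation test, p = 0.333, the smallest that the 6 assignments of 4 libraries allow). CpG 2, with 25851 peaks, lay closer to control 1, with 29226, than to CpG 1, with 13553. Peaks covered 12.4, 19.1, 3.33 and 11.5 Mb and had median lengths of 291, 341, 202 and 317 bp in control 1, control 2, CpG 1 and CpG 2. Genes with a promoter peak numbered 6130 ± 731 (SD, n = 2) in the control and 3760 ± 1988 (SD, n = 2) in the CpG libraries (exact permutation p = 0.333).

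Libraries of a condition shared on average little more of their peaks with each other than with the other condition, and the difference depended on which libraries were used. The Jaccard index, the base pairs shared by a pair of lists over those in either, was 0.368 for the control libraries and 0.164 for the CpG libraries. Control 2 and CpG 2 shared 0.386, the highest of the 6 pairs, and control 1 and CpG 2 shared 0.334. CpG 1 shared 0.121 with control 1 and 0.103 with control 2. The mean within conditions was 0.266 and between conditions 0.236, a difference of 0.0304, against 0.0110 and -0.0413 for the other 2 ways to split the 4 libraries into pairs. The difference changed sign without control replicate 1 (-0.0799) and without control replicate 2 (-0.0630), and was 0.00785 without CpG replicate 1 and 0.257 without CpG replicate 2.

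**Figure D3:**
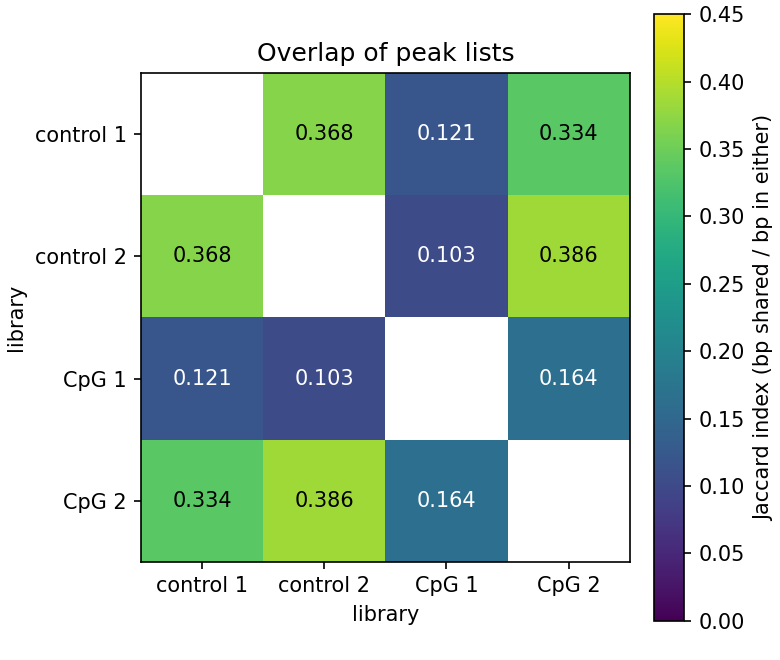
Jaccard index (base pairs shared over base pairs in either list) for each pair of the 4 anti-IRF5 libraries, on a colour scale with the value in each cell. Control 2 and CpG 2 have the highest value, 0.386, and control 2 and CpG 1 the lowest, 0.103.

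Introns held the largest share of peaks in both conditions, 51.0% ± 0.187 (SD, n = 2) in the control and 47.4% ± 2.49 (SD, n = 2) in the CpG libraries (exact permutation p = 0.333). A peak counted in every class that its annotation named, so the shares of the classes overlap. Intergenic regions held 27.5% ± 1.09 and 32.7% ± 5.81 (SD, n = 2 each, exact permutation p = 0.333). Promoters held 19.2% ± 0.782 and 18.0% ± 3.06 (SD, n = 2 each, exact permutation p = 1), a difference of -1.19 percentage points. It was -4.03 with lists of equal length (exact permutation p = 0.333) and -3.35 without CpG replicate 2, and it turned to 0.973 without CpG replicate 1 and to 1.53 with control 2 and CpG 2 alone, a comparison chosen after the data were seen. Exons held 11.4% and 9.58%, 5' untranslated regions 4.28% and 3.86%, and 3' untranslated regions 1.58% and 1.17% (exact permutation p from 0.333 to 1).

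Promoter-class peaks were called in both CpG libraries and neither control library at 139 genes, among them those of the cytokine interleukin 1 alpha and of the kinase p38 alpha, and 94 of the 139 had no overlapping control peak of any class. In the opposite direction there were 1026 genes, and 859 of the 1026 had no overlapping CpG peak. Of 55621 merged regions 638 were CpG-only, 4841 control-only and 5599 called in all 4 libraries, while 31112 were called in 1 library. The other ways of pairing the libraries gave 59 and 657, and 290 and 111 such promoter genes. Membership depended on the rule, as of the 127 CpG-only genes with a name 57 were CpG-only also by peaks within 1 kb and 38 by any nearest peak, and of the 908 control-only genes 478 and 362 were control-only. The lower number of peaks in CpG 1 limits what can be called in both CpG libraries. With 13553 peaks from each library there were 222 CpG-only and 467 control-only genes, and the authors' lists for whole conditions gave 676 and 3027.

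Il1a, the gene of interleukin 1 alpha (chromosome 2, 129141529 to 129151892, minus strand), had a CpG-only promoter peak with a fold enrichment of 7.67 in CpG 1 (129153649 to 129153864) and 9.30 in CpG 2 (129153611 to 129153877), and no overlapping peak in either control library. By the other rules Il1a was not CpG-only. CpG 1 had no peak within 1 kb of its start, and control 2 had 1 peak nearest to it, with a fold enrichment of 5.46. Mapk14, which encodes p38 alpha, shared its peak with the neighbouring Slc26a8, at a fold enrichment of 6.80 and 8.54. Faim, an inhibitor of Fas-induced cell death, had 8.67 and 8.66, and Ptprm, a receptor-type phosphatase gene, had 9.34 and 8.43. No control peak overlapped those of Mapk14, Faim and Ptprm. Still, Faim was the nearest gene of 1 peak, and Mapk14 and Ptprm of 4 to 6 peaks, in each control library. Gadd45a, a DNA damage response gene, had the highest fold enrichments of the named CpG-only genes, 11.7 and 21.2. At Gadd45a, Trpm7 and Abcc5 both control libraries had overlapping peaks that the authors' annotation put in another class, so for these genes the class and not the presence of a peak differed. The class followed the position of a peak's summit, as 92.4% to 93.4% of promoter calls had theirs within 2 kb upstream of the nearest gene's start. The counts without such genes, 94 and 859, were chosen after the data were seen. From the fixed lists, Ier3, an NF-kB target and immediate early gene, the ribosomal protein gene Rps9 and the interferon-stimulated ubiquitin ligase gene Trim21 were CpG-only too, and Ier3 and Rps9 had overlapping peaks in both control libraries.

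Among control-only genes Cd53, a leukocyte tetraspanin gene (chromosome 3, 106667236 to 106697465), had fold enrichments of 20.1 and 17.9 in control 1 and control 2, Mospd2 13.1 and 17.4, Rab7, a GTPase gene of late endosomes, 12.5 and 15.3, and Eif2s3y, on chromosome Y, 19.1 and 13.9. No CpG library had an overlapping peak at these. Apobec1, Rab11fip4os1, Mafk and Cd180 completed the 8 highest, and CpG 2 had an overlapping peak of another class at each. Control-only members of the fixed lists included the transcription factor genes Irf8 and Irf3, the antigen presentation genes Cd74, Ctss, H2-DMb1 and Cd40, and the lysosomal genes Lamp2 and Ctsa. Dendritic cell markers among them were Tcf4, Bst2, Batf3 and Id2, and Id2 had a peak within 1 kb of its start in both CpG libraries. Fcgr2b had overlapping peaks in both CpG libraries, and Tfrc, Rpl13 and Rpl8 in CpG 2, while Mlkl had a peak within 1 kb of its start in CpG 2. Further members were Mitf, Tnip1, Tab3, Pik3ap1, Nr4a1, Tnfsf9, Isg20, Cdc25c, Ccnd1, Bnip3, Cebpe, Ryr1, Ndufa4, Ndufv1 and Rpl15. Tnip1, Pik3ap1 and Nr4a1 were the nearest gene of peaks in both CpG libraries, as were Cd53, Rab7, Mafk, Cd180, Ctss and Tcf4 above.

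Leaving out a library drops a requirement of the rule, so these counts rise by construction, and the size of the rise shows how many items that library alone kept out. Without control replicate 1, control replicate 2, CpG replicate 1 or CpG replicate 2 there were 217, 366, 846 and 508 CpG-only promoter genes in place of 139. The control-only genes became 2461, 1995, 1150 and 2846 in the same order, in place of 1026. CpG-only regions rose from 638 to 1755, 5946 and 4926 without control replicate 2, CpG replicate 1 and CpG replicate 2. Control-only regions rose from 4841 to 18817 and 14080 without control replicate 1 and control replicate 2. They rose to 5303 and 11717 without CpG replicate 1 and CpG replicate 2.

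No gene list passed the test of its balance between CpG-only and control-only genes, which few of them could have passed. Inflammatory cytokines and chemokines had 1 CpG-only member, Il1a, and 1 control-only member, Tnfsf9, and NF-kB subunits and targets had 1 and 2. Antigen presentation and lysosome genes each had 0 CpG-only and 5 control-only members, of which Pdia3 and Lamp1 were named after their values were seen, against 127 CpG-only and 908 control-only named genes in all. Of the 24 lists 0 passed Fisher's exact test after adjustment and 0 had an unadjusted p under 0.05, the lowest being 0.230. Lists had at most 5 group-only members, so that 8 lists could have passed on their own if all members were CpG-only and 0 if all were control-only, and the result does not show that the lists were balanced. Without control replicate 2 a pair of lists passed, each at 5 CpG-only and 3 control-only members (odds ratio 8.87, adjusted p = 0.0450, Fisher's exact test). The 5 were Birc2, Ier3, Junb, Rel and Traf1 for NF-kB and Acod1, Il10, Il12b, Il1a and Il1b for cytokines, and the 3 were Cd40, Nfkb1 and Tnip1, and Cxcl16, Tnfsf10 and Tnfsf9, all named after their values were seen. All of the former except Ier3 and Il1a had a promoter peak in control 2, the library left out.

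The genes fixed beforehand included Irf5 itself (chromosome 6, 29526623 to 29541870). It had promoter peaks with fold enrichments of 3.65 in control 1, 11.9 in control 2 and 4.52 in CpG 2, and none in CpG 1, and was the nearest gene of 10, 7, 1 and 4 peaks in control 1, control 2, CpG 1 and CpG 2. Irf1 and the macrophage transcription factor gene Spi1 likewise had promoter peaks in all but CpG 1. Tlr9, Myd88, Tnf and Ccl3 had them in all 4 libraries. The cytokine genes Il12b, Il10, Il1b and Cxcl10 had them in all but control 1, where Il10 and Il1b had overlapping peaks of another class and Il12b and Cxcl10 none. The promoter peak at Il10 had the highest fold enrichment of these in control 2 (27.2) and CpG 2 (17.1), and in CpG 1, where it had 4.83, that at Il1b did (6.69). The hexokinase gene Hk2 had promoter peaks in control 1 and CpG 2, Irf7 and Nfkb1 in control 1, Nfkbia in CpG 2 and Actb in control 2. Hk2, Nfkbia and Actb had a peak within 1 kb of the start in every library, and so had Irf7 in control 2, Nfkb1 in CpG 2 and Spi1 in CpG 1. Il6 had no promoter-class peak but 1 within 1 kb in control 1, CpG 1 and CpG 2. Il12a, Ccl5 and Ifit1 were the nearest gene only of peaks farther away, in all 4 libraries. Isg15 had 1 peak nearest to it, in control 2, and the interferon beta gene Ifnb1 had 1, in CpG 2. Hk1 was not named in any of the lists.

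**Figure D4:**
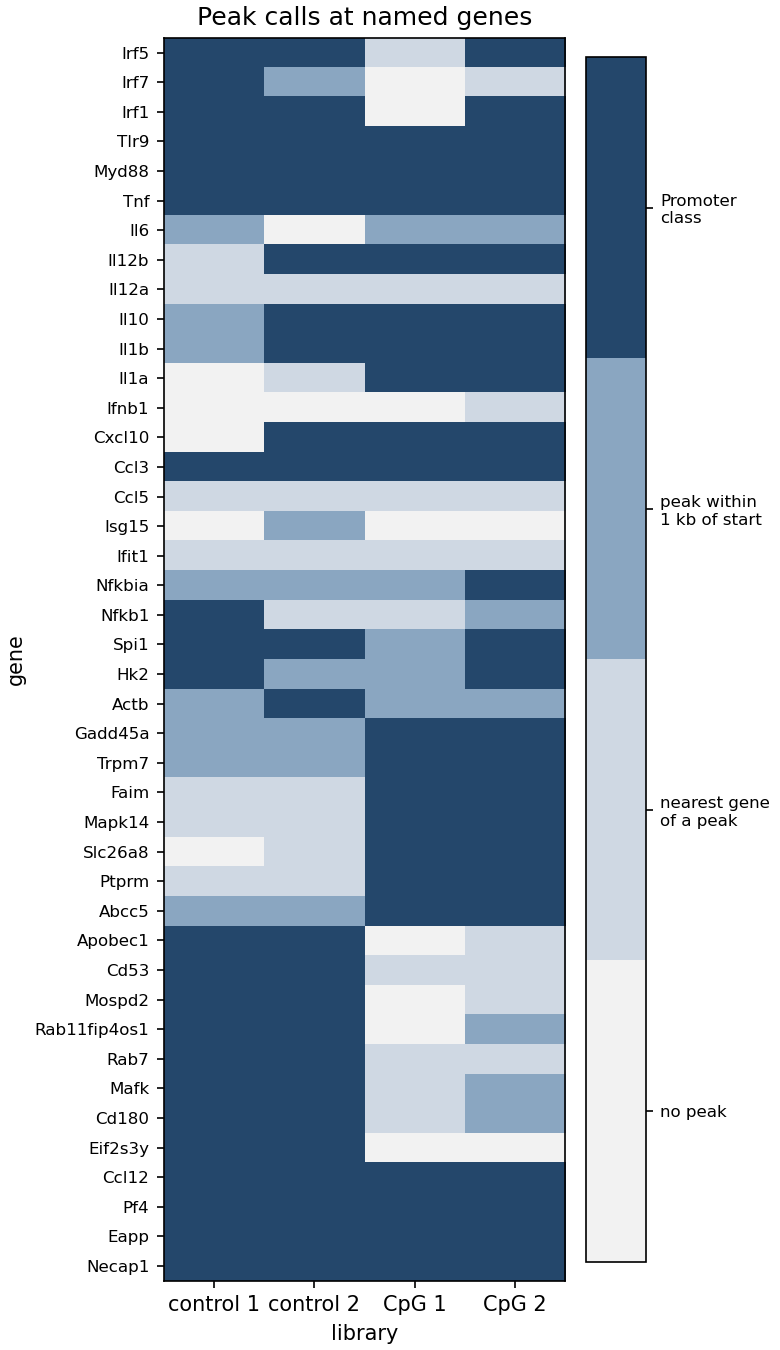
Peak calls at the fixed genes and at the highest CpG-only, control-only and shared promoter genes (vertical axis) in the 4 anti-IRF5 libraries (horizontal axis), with shades for no peak, a peak that has the gene as nearest, a peak within 1 kb of its start and a promoter-class peak. Ccl12, Pf4, Ccl3, Eapp and Necap1 have a promoter-class peak in all 4 libraries, and Il1a in both CpG libraries alone.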

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

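The tests of depth, enrichment and stimulation for the short CpG 1 list, those of the high control 1 peaks and the count of other splits were chosen after the result was seen, and the main tests of overlap between libraries were chosen before.

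Signal outside the compared chromosomes was found on the mitochondrial genome, which carried 8 peaks in control 1, 9 in control 2, 6 in CpG 1 and 6 in CpG 2. Within each list their fold enrichments ran from 1.13 to 1.93, from 1.13 to 1.75, from 1.86 to 3.16 and from 1.45 to 2.56, and in each the highest was at the peak nearest mt-Tp.

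CpG 1 had the fewest peaks, 13553 against 25851 in CpG 2. The estimated depth of CpG 1 over CpG 2 was 1.59, which argues against lower depth. The peaks that CpG 2 lacked against the control mean were 0.376 of those that CpG 1 lacked, but 0.215 against control 1 and 0.482 against control 2, too wide a spread to decide on CpG stimulation, which stays open. Over the 5599 regions called in all 4 libraries the median longest peak was 557, 868, 268 and 648 bp in control 1, control 2, CpG 1 and CpG 2, and the CpG 1 to CpG 2 ratio of 0.414 is in line with weaker enrichment in that library. Since the same peaks are shorter there, CpG 1 may have failed to reach some of the 4841 control-only regions. All of these were missing from CpG 2 as well, and without CpG replicate 1 there were 5303. A weak CpG 1 alone therefore does not account for them. The regions called in every library but CpG 1 numbered 6769.

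Control 2 and CpG 2 shared more of their peaks (Jaccard index 0.386) than the control libraries shared with each other (0.368). With lists of equal length the gap was 0.0460, which argues against list length as the cause. The test set for a source common to libraries of the same number was whether CpG 1 shared more with control 1 than with CpG 2, and the difference was -0.0482 at equal length. That test assumed a source stronger than any effect of the condition, and across conditions same-numbered libraries did share more, 0.137 against 0.124 for CpG 1 and 0.425 against 0.344 for CpG 2, a comparison added afterwards, so this source stays open. No biological explanation was tested.

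Control 1 had high-fold peaks at gene starts, which made up 26.5% of its 200 highest peaks against 11.5%, 11% and 15.5% in control 2, CpG 1 and CpG 2, led by a peak at Rpl32 and Snora7a (chromosome 6, 115784863 to 115787505) with a fold enrichment of 99.9 in control 1. The first test of the shared IgG background as a source took the places of these 53 promoter peaks in control 2, called against the same IgG library, and their median percentile of 97.0 (86.9 in CpG 2 and 23.99 in CpG 1) went with that explanation, though the Rpl32 place lay at 71.4 there and 7 of the 10 highest from 30.3 to 82.5, with 1 not called. That median shows only that these places tended to rank high in control 2 too. A background shared by both control libraries cannot by itself give the 26.5% of control 1 beside the 11.5% of control 2. The comparison of these shares was added once the first outcome was known. Transposition at open starts of broadly used genes was tested by their share among these genes, with an odds ratio of 6.54 and Fisher's exact p = 0.0436 on only 2 genes, Rpl10 and Rpl32, and a minimum of 5 genes that leaves it undecided was set after this outcome. The IgG background thus does not explain why control 1 stands apart from control 2, though it may add to peaks in both. Transposition at open starts could not be excluded, and no biological explanation was tested.

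The real split of the libraries gave 1165 promoter genes called in both libraries of one side only, and the highest of the other splits 716. It was thus 1 of 3 with so many, but 3 splits are too few for a share under 0.05.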

How the results depend on the processing

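The tests on control 2 and CpG 2 alone, on other gene backgrounds and on overlapping peaks were chosen after seeing the data, and the other alternatives before. Of 110 alternatives for the results of whole comparisons 67 stayed the same, 39 moved and 4 reversed. To stay the same meant to keep the direction, or for counts to stay within 1.5 times. An overlap that kept its direction counted as moved where it shifted by more than the SD of the within-condition pairs. The cause was not tested except where given. Of 1020 for single genes and lists 702 stayed within 1.5 times and 318 moved.

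With lists of equal length the promoter share difference grew from -1.19 to -4.03 percentage points (exact permutation p = 0.333), control-only regions fell to 1613, CpG-only promoter genes were 222, control-only promoter genes 467, and the gene lists that passed 7 in either condition, 5 in the control and 5 in the CpG libraries. By any nearest peak these were 342 and 1717 genes, and 7, 6 and 4 lists. The authors' lists of whole conditions gave 2637 CpG-only and 16825 control-only regions, and 676 and 3027 genes. Control 2 and CpG 2 alone gave 7085 and 19738 regions, 1214 and 2696 genes, and a promoter share 1.53 percentage points higher with CpG. Both settings ask for 1 list per condition in place of 2, so more items qualify by construction. A protein-coding background left 3, 1 and 3 lists, since its genes are bound more often, and the RefSeq background raised those of the control libraries to 16. For the results of whole comparisons the stricter q, the wider overlap (run for regions and overlap) and all contigs (not run for enriched lists or overlap) moved no count by over 1.5 times.

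Leaving out each library in turn gave a peak ratio of 0.407 to 0.777, a within-minus-between overlap of -0.0799 to 0.257, a promoter share difference of -3.35 to 0.973 points, 865 to 5946 CpG-only and 5303 to 18817 control-only regions, and 217 to 846 CpG-only and 1150 to 2846 control-only genes. Lists that passed numbered 11 to 13, 10 to 13 in the control and 4 to 10 in the CpG libraries, and lists out of balance 0 to 2, both of the 2 without control replicate 2. Leaving out a library changed the enriched lists of the other condition through the adjustment alone. With 1 library left in a condition more items qualify by construction.

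Libraries of the conditions share only a number in the labels, and nothing says that it pairs them. With the number as a block the peak ratio was 0.567 (exact sign-flip p = 0.5, the smallest possible) and 0 lists were out of balance (lowest adjusted p 0.276 by the Cochran-Mantel-Haenszel test). Deviations of same-numbered libraries correlated at 0.0353 over regions and 0.000300 over promoter genes. Of 55621 regions 31112 were called in 1 library and so had no deviation in the other condition. This holds the correlation down, so the low values do not argue against pairing. The motif alternatives were not run. Unknown depth limits every statement that a peak is missing in a library.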

Other observations

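The tests of the cytokine and interferon-stimulated lists were chosen before their outcomes, and the count over all lists was chosen after the results were seen.

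Peaks anywhere in the genome were also grouped by their nearest gene. Peaks nearest IRF family genes made up 0.855 and 0.670 per 1000 peaks in control 1 and control 2, and 0.148 and 0.503 in CpG 1 and CpG 2. Macrophage identity genes, such as those of F4/80 and complement C1q, took 6.60, 5.63, 4.06 and 5.38 per 1000, and with lists of equal length 6.71, 6.49, 4.06 and 5.46. Lysosome and phagocytosis genes took 4.28, 3.54, 2.66 and 3.52, but 4.72, 4.57, 2.66 and 4.72 at equal length, where CpG 2 reached the control libraries. The type I interferon genes, which had no promoter peak, took 0.103, 0.134, 0.369 and 0.271 per 1000, but these are only 3, 5, 5 and 7 peaks, and 0, 1, 5 and 4 at equal length. In each of these lists except the equal-length lysosome list both CpG libraries lay on one side of both control libraries, with an exact permutation p of 0.333. Of the 24 lists 9 lay lower and 2 higher with CpG in whole lists, where chance alone gives a share of 0.333 for both directions together.

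A first hypothesis was that CpG shifts IRF5 towards inflammatory cytokine and chemokine genes, so that peaks near them take a larger share of both CpG lists than of both control lists. They took 3.76 and 3.67 per 1000 peaks in control 1 and control 2, and 5.09 and 3.98 in CpG 1 and CpG 2, and the lower CpG library lay 0.221 above the higher control library. In number they were fewer with CpG, 110 and 137 against 69 and 103, as the CpG lists are shorter. At equal length the values were 3.98, 3.84, 5.09 and 4.65. The order of the shares is in line with the hypothesis in whole lists and at equal length, but with an exact permutation p of 0.333, the smallest possible, it may as well be chance.

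A second hypothesis was that peaks near interferon-stimulated genes take a larger share with CpG in the same way. They took 2.02, 1.85, 1.62 and 2.13 per 1000 peaks, and 2.07, 1.70, 1.62 and 1.99 at equal length. In whole lists the lower CpG library lay below the higher control library, at -0.395, so the order that the hypothesis needs was not found. CpG 2 lay above both control libraries in whole lists but between them at equal length. Without any change the order fails in 5 of the 6 assignments, so the test leaves the hypothesis open.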
